A study of Mus musculus with 4 samples.

How the data were processed

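Single-cell RNA was measured in 4 libraries of mouse skin, 2 of Cre-negative control mice (Ctrl) and 2 of DKO-K15 mice, which carry floxed Jun and Junb alleles and a mifepristone-inducible Cre under the K15 promoter. Per the labels' protocols, mice received 1 topical dose of 50 µg DMBA (a mutagen that starts skin tumours) at 6 weeks of age, mifepristone at 2 mg for 5 days at 8 weeks, and then 4 µg TPA (a phorbol ester that promotes them) 3 times a week for 15 weeks. Skin was taken 48 h after the last TPA dose and digested with Liberase and DNase at 100 µg/ml each for 1 h at 37 °C. Up to 30000 cells were loaded per library for droplet capture with a kit that reads the 5′ end of transcripts, and all libraries were sequenced together with paired reads of 150 bp. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

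The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, per the labels. Reads were aligned and counted with Cell Ranger 8.0.1 on the mm10 genome, per the submitters' processing notes. The barcode calling settings and the annotation release are not given in the sources used here. All 4 matrices list the same 32285 genes by Ensembl identifier and symbol, with 40 symbols shared by 2 identifiers, and 32158 of the identifiers were found in the reference annotation used for positions. The matrices held 18250 barcodes and 144608778 UMIs. Ctrl libraries 1 and 2 held 4862 and 2763 barcodes with 31218484 and 27285015 UMIs, and DKO libraries 1 and 2 held 6648 and 3977 barcodes with 45594529 and 40510750 UMIs. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 93.3 in Ctrl and 37.0 in DKO, so each was counted as 1 replicate. Among sex-linked genes, Xist stood at 0.128, 0.0367, 0.0658 and 0.0494 CPM (counts scaled to a common library total) in Ctrl 1, Ctrl 2, DKO 1 and DKO 2, while Ddx3y stood at 67.0, 54.8, 43.5 and 46.3, Eif2s3y at 48.0, 49.7, 54.7 and 59.4, Kdm5d at 17.4, 19.9, 20.4 and 18.7, and Uty at 48.6, 56.5, 53.2 and 48.4.

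Barcodes with under 200 genes or over 15% mitochondrial UMIs were left out. Doublets were scored as in Scrublet, from 2 simulated doublets per cell, and the highest-scoring cells were removed, 0.4% of a library per 1000 barcodes, which took 95, 31, 177 and 63 cells from Ctrl 1, Ctrl 2, DKO 1 and DKO 2. Kept cells numbered 3862, 2289, 6137 and 3464, in all 15752 cells with 131731519 UMIs, at a median of 2971.5, 3880, 2628 and 3428.5 UMIs per cell. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes (T cell receptor and immunoglobulin segments, mitochondrial, ribosomal and sex-linked genes excluded) gave 30 principal components and a shared-neighbour graph of 20 neighbours, which was clustered by the Leiden algorithm at resolution 1.0. Immune clusters were clustered again on their own genes at the same resolution, and keratinocytes and T cells were clustered within themselves at resolution 0.6. No cell annotation was used here other than these rebuilt names. Clusters were named only from marker lists fixed before the data were examined, by the mean log2 fold of the leading markers detected in at least 10% of the cluster's cells. A name needed at least 3 raised markers and no other class with more markers among the top 10 genes. This scoring, and a margin of 1.1 times over the next class at a tie, were set after the data were seen. Clusters without a name held 5.96% and 7.78% of kept cells in the Ctrl libraries and 6.52% and 3.20% in the DKO libraries, and 2.97%, 5.23%, 8.29% and 7.37% of keratinocytes could not be placed in a compartment. The compartment of the hair follicle and sebaceous marker list held hair follicle clusters by their leading genes and is written as hair follicle cells. Classes are written by their plain names, and each stands for cells that resemble that type by these markers.

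Cells are not replicates, so UMIs were summed per library and class. A class was tested where every library held at least 20 of its cells, which neutrophils, dendritic and Langerhans cells and lymphatic endothelial cells did not meet. Sums were tested with edgeR's quasi-likelihood F test (TMM scaling, filterByExpr, robust dispersion, genotype as the only term), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Changes are log2 ratios of DKO over Ctrl with their standard error, n = 2 libraries per group throughout, and levels beside them are TMM-scaled CPM as mean and SD. Levels in classes that were not tested, and the share of a gene's UMIs that a class held, use plain CPM. Shares of classes and compartments were tested with the same model on cell counts, and shares of cells in a single library carry exact Clopper-Pearson intervals at 95%, which cover counting error only. A share of 0 is given the limit of 3 counts of the total instead. A fold against a group with no UMI was computed against a floor of 3 counts over the group, and a fold against 1 to 3 UMIs is given as a ratio with its counting interval. An exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.333. For depth-matched shares each cell was thinned to 1000 UMIs, which left out 689, 506, 1356 and 799 cells.

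Gene lists fixed before the data were examined were tested with limma's camera at its preset inter-gene correlation, where at least 5 members were measured, and again with an estimated correlation and with fry. Fry asks whether a list's genes move one way on balance and, unlike camera, sets no list against other genes. The lists were AP-1 family, psoriasis-type epidermal genes, neutrophil-attracting factors, IL-17 and IL-23 axis, inflammatory cytokines and NF-kB feedback, type I interferon response, antigen presentation and interferon-gamma, basal and stem cell keratinocyte genes, terminal differentiation, proliferation, squamous carcinoma-associated genes, EGFR ligands and feedback, extracellular matrix, inflammatory fibroblast genes, neutrophil granule and oxidative burst, tumour-type neutrophil genes, cytotoxic lymphocyte, regulatory and exhausted T cell, type 2 immunity and alternative activation, endothelial activation, hypoxia and glycolysis, NRF2 and oxidative stress, DNA damage and p53, dissociation and handling stress, and sex genes (given above per library). Genes were named by a rule fixed at the same time: the 8 with the smallest p among those higher and the 8 among those lower in whole skin, keratinocytes and neutrophils, 4 and 4 in every other tested class, each past the threshold and with both DKO libraries on the same side of both Ctrl libraries, up to 4 members of each list by smallest p, and Jun and Junb always. Receptor and immunoglobulin segments, predicted genes, mitochondrial and ribosomal protein genes and sex-linked genes were counted but not named. Genes on the neutrophil marker list that are named in another class carry their level in neutrophils. The AP-1 family and the handling stress list share Fos, Fosb and Atf3, and the AP-1 list holds the targeted Jun and Junb. Calls of these lists in a class are thus not independent of each other.

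The statistics were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. Each gene was given the dispersion of the fitted trend at its level, so spread did not differ further from gene to gene. The recovered parts hold for that setting and need not hold for the real counts. Of 2-fold and 4-fold changes the test recovered 51% and 89% in keratinocytes (14407 genes), 24.7% and 76% in whole skin (17031 genes), 28% and 78.7% in macrophages and monocytes, 21% and 79.3% in T cells, 45.7% and 87.7% in fibroblasts and 35.3% and 85% in endothelial cells. Camera called all 3 changed lists in each of these classes at the preset correlation and 0 with an estimated correlation. A list lost with an estimated correlation is therefore not shown to be unchanged. Simulated genes varied independently, so the preset correlation was not tested for genes that vary together. A 16-fold change of a class's share was called in 89% of simulations.

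Alternatives planned before the data were examined were a mitochondrial limit of 10% or 25%, at least 500 genes, no doublets removed or the top 8% removed, resolutions 0.5 and 2.0, DESeq2-type size factors, the DESeq2 Wald test, no filter on genes, equal numbers of cells per library, thinned counts for Jun and Junb, other denominators, a replicate block, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other group. Cells were clustered and named again under each limit on cells or doublets and at each resolution, so a class there can hold other clusters. Added after seeing the data were keratinocytes outside the hair follicle compartment, whole skin without hair follicle cells or without neutrophils, a crossed pairing, and thinned counts for all genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.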

Results

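Whole skin of mice treated with a tumour-starting mutagen and a tumour-promoting phorbol ester was profiled cell by cell, with 2 libraries from Cre-negative controls (Ctrl) and 2 from mice in which Jun and Junb can be deleted by the K15-driven Cre (DKO). Jun and Junb encode subunits of the AP-1 transcription factor. The libraries held between 27285015 and 45594529 UMIs. Before filtering, Ctrl 1, Ctrl 2, DKO 1 and DKO 2 had medians of 2194.5, 2786, 2585 and 3019 UMIs per barcode and 5.64%, 4.09%, 2.75% and 2.41% mitochondrial UMIs. The filters kept 79.4% and 82.8% of barcodes in Ctrl and 92.3% and 87.1% in DKO. The comparison of DKO with Ctrl asks what loss of both genes did to epidermal inflammation, neutrophil entry and squamous tumour growth, the subjects named in the title of the series.

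The targeted genes stood lower in DKO skin as a whole, by amounts that did not pass the test, and Jun fell in keratinocytes. Jun (ENSMUSG00000052684, mm10 chromosome 4, 95049034 to 95052222) measured 1383, 885, 445.8 and 500.5 TMM-scaled CPM over all cells of Ctrl 1, Ctrl 2, DKO 1 and DKO 2 (log2 change of -1.26 ± 0.26 SE, n = 2 per group, edgeR adjusted p = 0.0927). Junb (ENSMUSG00000052837, mm10 chromosome 8, 84974484 to 84978718) measured 771.4, 420.7, 303.2 and 326.8 (-0.92 ± 0.32, adjusted p = 0.154). In keratinocytes Jun fell from 1076 ± 510 (SD) to 285 ± 9.76 (-1.92 ± 0.36, adjusted p = 0.0377), and Junb stood at 495 ± 289 and 186 ± 14.1 (-1.41 ± 0.44, adjusted p = 0.0785). The labels do not say which part of either gene is removed, so reads from the 5′ end of a deleted allele cannot be told from those of an intact one.

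Within keratinocytes the fall of Jun passed the test in suprabasal cells (-2.54 ± 0.33, adjusted p = 0.00782), while basal cells (-1.54 ± 0.39, adjusted p = 0.0909) and hair follicle cells (-1.75 ± 0.32, adjusted p = 0.0802) missed it. Junb did not pass in suprabasal (-1.23 ± 0.37, adjusted p = 0.0812), basal (-0.99 ± 0.34, adjusted p = 0.158) or hair follicle cells (adjusted p = 0.244). Compartments were not tested against each other. Outside keratinocytes Jun fell in T cells (-1.21 ± 0.25, adjusted p = 0.0319), and Jun (-1.08 ± 0.19, adjusted p = 0.00233) and Junb (-1.30 ± 0.18, adjusted p = 0.000358) fell in endothelial cells. Jun did not pass in fibroblasts (0.19 ± 0.24, adjusted p = 0.722), macrophages and monocytes (-0.21 ± 0.26, adjusted p = 0.728) or skeletal muscle (0.11 ± 0.17, adjusted p = 0.901). Junb did not pass in mural cells (-2.35 ± 0.45, adjusted p = 0.101), macrophages and monocytes (-0.48 ± 0.22, adjusted p = 0.26), fibroblasts (-0.38 ± 0.21, adjusted p = 0.415), T cells (-0.13 ± 0.29, adjusted p = 0.858) or muscle (-0.90 ± 0.58, adjusted p = 0.745). After thinning every cell to 1000 UMIs, 42.7% and 24.2% of Ctrl keratinocytes and 18.3% and 14.6% of DKO keratinocytes held a Jun UMI, against means of 36.2% ± 7.89 and 53.2% ± 0.616 (SD, n = 2) of fibroblasts. Every class kept Jun UMIs in DKO skin, and none of them is known to lack the gene, so free RNA could not be measured from it.

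Several of these calls changed under the alternatives. Jun lost its call in keratinocytes without DKO 1 (-1.86 ± 0.53, adjusted p = 0.166) and without DKO 2 (-1.94 ± 0.53, 0.244), where the change stayed as large and its error grew, as in suprabasal cells without DKO 1 (-2.65, 0.0783) and DKO 2 (-2.44, 0.112). In endothelial cells Jun was lost without Ctrl 1 (0.1), DKO 1 (0.17) and DKO 2 (0.255), and Junb without DKO 1 (0.12) and DKO 2 (0.108) and with thinned counts (-0.73, 0.289). In T cells Jun was lost under a mitochondrial limit of 10% (0.0672), with no doublets removed (0.0708), at resolution 2.0 (0.0661) and with thinned counts (-0.80, 0.342). Junb in keratinocytes passed without Ctrl 1 (-0.63, adjusted p = 0.0436), without Ctrl 2 (-1.92, adjusted p = 0.00497), under a mitochondrial limit of 10% (adjusted p = 0.0412), with thinned counts (adjusted p = 0.00659) and by DESeq2 (adjusted p = 0.00269). Without Ctrl 2 Jun (-1.54, adjusted p = 0.0141) and Junb (-1.29, adjusted p = 0.0146) also passed in whole skin, as did Jun by DESeq2 (adjusted p = 0.000593), and Jun (-0.57) and Junb (-0.76) in macrophages and monocytes and Junb (-0.59) in fibroblasts. Jun in basal cells passed without Ctrl 2 (-1.94), under a mitochondrial limit of 10% (-2.07), with no doublets removed (-2.05), at resolution 2.0 (-1.65), with thinned counts (-1.69), with no filter and by DESeq2. Jun in hair follicle cells passed without Ctrl 1 (-1.20) and Ctrl 2 (-2.13), under the limit of 10% (-2.12), with no doublets removed (-1.69), with a replicate block (-1.69), with thinned counts (-1.23), with no filter and by DESeq2. Junb passed in 5, 3 and 2 of the 13 alternatives in basal, suprabasal and hair follicle cells, in each of these also without Ctrl 2. Junb passed in muscle without DKO 2 (-1.96), and Junb in mural cells without each library in turn (-2.37, -2.31, -2.81 and -1.93).

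**Figure D1:**
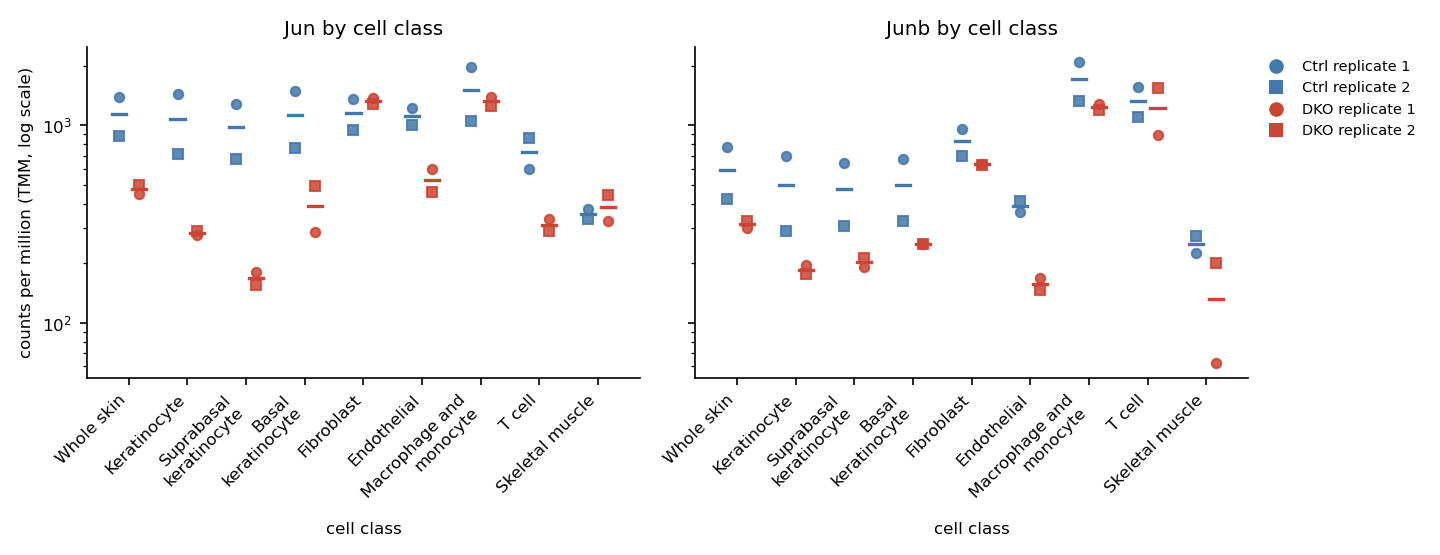
Jun and Junb per library and cell class in TMM-scaled CPM, on a log scale, 1 point per library and a bar at each group's mean. In keratinocytes Jun averaged 1076 in Ctrl and 285 in DKO.

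Neutrophils rose in DKO skin, and no other class passed the test for its share. They made up 0.104% (interval 0.0282 to 0.265) and 0.262% (0.0963 to 0.57) of cells in Ctrl 1 and 2, and 2.53% (2.15 to 2.95) and 3.90% (3.28 to 4.6) in DKO 1 and 2, with 4, 6, 155 and 135 cells. The mean rose from 0.183% ± 0.112 to 3.21% ± 0.97 (log2 change of 4.19 ± 0.81, edgeR adjusted p = 0.00129). Of immune cells they were 0.877% and 4.62% in Ctrl and 21.2% and 37.0% in DKO. Without Ctrl 1 (3.60, adjusted p = 0.202) or Ctrl 2 (4.92, adjusted p = 0.0577) the call was lost.

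Antigen-presenting dendritic and Langerhans cells were 2.49% and 0.830% of cells in Ctrl and 0.424% and 0.375% in DKO (-2.06 ± 0.73, adjusted p = 0.0794). Keratinocytes were 42.7%, 61.8%, 60.2% and 61.9% (0.22 ± 0.62, adjusted p = 0.865) and fibroblasts 17.7%, 6.51%, 10.8% and 11.4%. Macrophages and monocytes were 4.40%, 1.75%, 5.67% and 4.85% (0.77 ± 0.66, adjusted p = 0.458), T cells 4.79%, 2.80%, 3.23% and 1.18%, and endothelial cells 5.10%, 5.24%, 3.57% and 3.35%. An unnamed cluster that leads with Sct, Tgm6 and Krt90 held 0 cells in either Ctrl library and 151 and 74 in DKO, or 2.46% and 2.14%. A larger unnamed cluster that leads with Cxcl9, Aldh3a1 and Fst held 219, 178, 208 and 37 cells in Ctrl 1, Ctrl 2, DKO 1 and DKO 2. Both scored highest as keratinocytes, so the keratinocyte shares, compartments and tests leave them out. Fst is on the hair follicle list.

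Among keratinocytes the suprabasal share fell from 70.1% and 57.4% in Ctrl to 27.1% and 27.7% in DKO (-1.22 ± 0.21, adjusted p = 0.0229). Hair follicle cells were 2.18% and 11.8% in Ctrl and 39.8% and 46.4% in DKO (2.63 ± 0.95, adjusted p = 0.0945), and basal cells 24.7%, 25.6%, 24.8% and 18.5%. Clusters of the hair follicle compartment lead with hair genes such as Shh, Krt71 and Krt35, and a cluster that leads with the lipid genes Fa2h, Far2 and Elovl3 (34, 36, 77 and 32 cells) was not placed in it. A cluster with Cst6 and Krt79 among its leading genes was named suprabasal (96, 148, 55 and 34 cells in the same order). So was another with both genes (134, 89, 47 and 11). Both genes are on the hair follicle list, and the suprabasal scores were only slightly higher (3.43 against 3.21, and 2.81 against 2.46). The suprabasal and hair follicle shares rest on this naming. The suprabasal marker Flg2, which encodes a cornified envelope protein, itself fell within suprabasal cells, so the naming of that compartment is not independent of the genotype. The suprabasal call was lost without DKO 1 (adjusted p = 0.138), without DKO 2 (adjusted p = 0.155), at a clustering resolution of 0.5 and with a replicate block. The change of the hair follicle share was 1.87 without Ctrl 1 and 4.30 without Ctrl 2. Under a mitochondrial limit of 10% that share stood at 27.6%, 38.8%, 49.4% and 52.7% (0.62, adjusted p = 0.0487). Cells were clustered and named again under that limit, which only removes cells. The larger Ctrl shares thus mean that other clusters took the hair follicle name there.

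**Figure D2:**
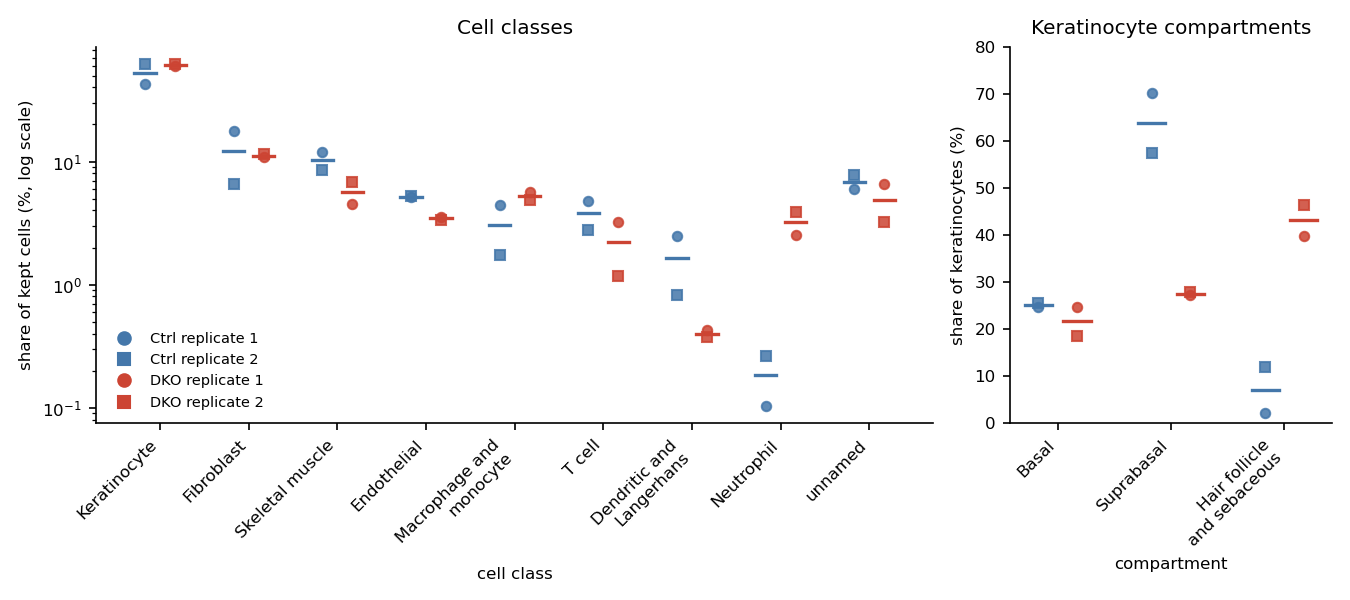
Share of kept cells in each class and of keratinocytes in each compartment, in percent, 1 point per library. Neutrophils lie between 0.104% and 0.262% in Ctrl and between 2.53% and 3.90% in DKO.

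In whole skin, with the cells of a library summed, no single gene passed, while the psoriasis-type and proliferation gene lists stood higher. Of 17366 genes, edgeR called 0, with 5185 at an unadjusted p under 0.05, and DESeq2 called 2733. The smallest adjusted p was 0.0757, shared by Sprr2b and Selenbp1. The call count rose to 5150 without Ctrl 2, 362 with no filter on genes and 724 with thinned counts, and was 1 without Ctrl 1 and 10 with a replicate block. In 66.0% of genes the groups did not overlap, where chance gives 33.3%. All list counts that follow were 0 over all genes for this reason, and no call at the preset correlation held with an estimated one, the lowest adjusted p being 0.638.

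Psoriasis-type epidermal genes (keratins, antimicrobial proteins and small cornified proteins of inflamed skin) were called higher as a list (adjusted p = 1.8e-07): 23 of 25 members stood higher, 10 rising when adjusted over the list alone, with a median log2 change of 2.39. Proliferation genes were called higher (adjusted p = 6.91e-09, 25 of 25 higher, 0 passing over the list alone, median 1.18), as were neutrophil granule and oxidative burst genes (adjusted p = 0.000166, 6 of 14, median 1.01) and NRF2 and oxidative stress genes (adjusted p = 0.00845, 6 of 13, median 0.42). Without hair follicle cells the proliferation call was lost (adjusted p = 0.715, median 0.07), and without neutrophils the granule genes kept theirs (adjusted p = 0.00162).

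Lower lists were led by dissociation and handling stress, the genes that warm digestion induces (adjusted p = 3.42e-08, 16 of 16 lower, 10 falling when adjusted over the list alone, median -1.41), and antigen presentation and interferon-gamma (adjusted p = 2.39e-06, 20 of 20 lower, 9 over the list alone, median -0.91). The AP-1 family was called lower (adjusted p = 0.000419, 7 of 13 over the list alone, median -1.17), and so were basal and stem cell keratinocyte genes (adjusted p = 0.000307, 5 of 17, -0.75), EGFR ligands and feedback (adjusted p = 0.00845, 6 falling and 1 rising of 15, -0.75), terminal differentiation (adjusted p = 0.0104, 10 falling and 2 rising of 22, -0.94), cytotoxic lymphocyte genes (adjusted p = 0.0104, 0 of 12 passing by either count, -1.36), hypoxia and glycolysis (adjusted p = 0.0104, 7 of 18, -0.39) and DNA damage and p53 (adjusted p = 0.0308, 2 falling and 1 rising of 14, -0.46). Cytotoxic genes lost the call without Ctrl 1 (adjusted p = 0.269), terminal differentiation without Ctrl 2 (0.225), and DNA damage without DKO 2 (0.0669).

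The remaining 11 lists were not called in whole skin. Their median log2 changes were 1.71 for neutrophil-attracting factors (adjusted p = 0.105), 0.24 for type I interferon response (0.711), 0.16 for tumour-type neutrophil genes (0.978), 0.04 for type 2 immunity and alternative activation (0.978), 0.03 for squamous carcinoma-associated genes (0.711), -0.29 for endothelial activation (0.591), -0.32 for extracellular matrix (0.711) and -0.55 for regulatory and exhausted T cell genes (0.0927). The IL-17 and IL-23 axis had a median of -0.27 and a mean of 0.20 (adjusted p = 0.404, lower), inflammatory cytokines and NF-kB feedback -0.03 and 0.60 (0.973, higher), and inflammatory fibroblast genes -0.32 and 0.03 (0.747, lower), so that median, mean and test differ in sign. Adjusted over the list alone, 1 neutrophil-attracting, 2 IL-17 axis, 2 cytokine, 3 squamous, 1 inflammatory fibroblast, 1 type 2 and 3 endothelial activation genes were higher. By the same count 1, 1, 1, 1 and 2 genes of the IL-17 axis, cytokine, squamous, inflammatory fibroblast and endothelial activation lists were lower, with 3 tumour-type and 2 regulatory genes. Leaving out DKO 1 gave a call to neutrophil-attracting factors (adjusted p = 0.000255) and to regulatory genes (0.0108), leaving out Ctrl 2 to regulatory genes (0.0371) and extracellular matrix (0.00414), and leaving out Ctrl 1 to extracellular matrix in the other direction (0.0382).

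DKO keratinocytes gained Sprr2d, a cornified envelope protein (9.03 ± 2.89 to 233 ± 33.2 CPM, log2 change of 4.67 ± 0.28, edgeR adjusted p = 0.0347), and its paralog Sprr2b, which went from 1 to 1574 UMIs (ratio 711, counting interval 127 to 28100). The cystine transporter gene Slc7a11 rose by 4.20 ± 0.21, from 1.39 to 26.1, the receptor gene Kit by 3.48 ± 0.21, the Wnt-processing gene Porcn by 2.09 ± 0.14, and the hair keratin-associated genes Krtap8-1 and Krtap7-1 by 6.29 ± 0.39 and 6.24 ± 0.40. Flg2 fell by 8.45 ± 0.20 (99.5 ± 12.4 to 0.279 ± 0.0296, adjusted p = 0.00655). Sprr4 (-3.00 ± 0.14), the endothelin gene Edn2 (-3.31 ± 0.19), and Abi3bp, Vwa2, Atp6v1b1, Slc46a2 and Enox1 (between -2.23 and -3.52) also fell. Reads of the Sprr2 and Krtap families can be shared between paralogs. Dcn, a fibroblast marker, was also higher (45.7 ± 8.63 to 360 ± 16.9).

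In all, 1560 genes rose and 1764 fell of 14642, and 6545 had an unadjusted p under 0.05. The groups did not overlap in 75.9% of genes, where chance gives 33.3%. Different cells made up the class in the 2 groups: the largest Ctrl cluster, which leads with Krt77, held 673 and 427 Ctrl and 31 and 8 DKO cells, while clusters that lead with Shh and with Sprr2b held 16 and 35, and 4 and 56, Ctrl cells against 690 and 283, and 459 and 392, DKO cells. Without DKO 1 or DKO 2 edgeR called 0 genes (3831 and 2765 at an unadjusted p under 0.05), so every gene call named for keratinocytes was lost there, and without Ctrl 2 the calls numbered 5544. Outside the hair follicle compartment 362 genes rose and 548 fell of 13523.

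Psoriasis-type genes rose in keratinocytes (camera adjusted p = 5.8e-06, adjusted p = 0.44 with an estimated correlation, median 2.13). Of 22 members, 9 rose and 1 fell, or 11 and 1 adjusted over the list alone. S100a9, an antimicrobial calcium-binding protein, rose from 20.6 ± 21.1 to 2814 ± 327 CPM (7.08 ± 1.03) beside 33294 ± 1310 plain CPM in DKO neutrophils. The skin protease gene Klk13 rose by 2.70 ± 0.39 and Cd24a by 0.83 ± 0.10. A UMI of S100a9 was found in 41.0% of DKO keratinocytes and in 14.4% of DKO fibroblasts, where free RNA and expression could not be told apart. S100a9 lost its call with no filter on genes (adjusted p = 0.0836) and with thinned counts (0.0824).

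Proliferation genes rose in keratinocytes (camera adjusted p = 8.08e-09, adjusted p = 0.44 with an estimated correlation, 11 of 25, 23 adjusted over the list alone, median 1.30). Within compartments the medians were smaller, at 0.40 in basal (0.00425, adjusted p = 0.865 with an estimated correlation, 0 of 25 by either count), 0.33 in suprabasal (not called, 0.0875) and 0.05 in hair follicle cells (not called, 0.178). Among the members that rose in keratinocytes were Rrm2 (1.45 ± 0.13), which supplies nucleotides for DNA synthesis, and the replication helicase gene Mcm2 (1.09 ± 0.10). NRF2 and oxidative stress genes rose (0.00717, adjusted p = 0.479 with an estimated correlation, 6 of 13 by either count, median 0.47). They included the glutathione synthesis genes Gclm (1.11 ± 0.12) and Gclc (0.94). Of neutrophil granule genes 3 of 8 rose (4 adjusted over the list alone), such as the iron-binding Lcn2 (3.83 ± 0.71, lost with no filter on genes at 0.115). That list was not called (adjusted p = 0.0922) except without DKO 2 (0.0261).

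Genes of barrier formation and stem cells fell in keratinocytes. Terminal differentiation fell (camera adjusted p = 0.00224, adjusted p = 0.44 with an estimated correlation, median -1.58), and among keratinocyte lists it alone passed fry (adjusted p = 0.0186). Of its 22 members 11 fell, or 12 with 3 rising when adjusted over the list alone. It was not called within basal (median -0.35, 0.626) or suprabasal cells (-0.35, 0.42). The involucrin gene Ivl fell from 91.9 ± 18.2 to 32.4 ± 4.35 CPM, and Cdsn, which holds corneocytes together, by 4.43. Basal and stem cell genes fell (5.8e-06, adjusted p = 0.44 with an estimated correlation, 10 of 17, 12 over the list alone, median -1.10). They included Krt15 (-1.62 ± 0.28), the keratin whose promoter drives the Cre, and the hair follicle stem cell gene Sox9 (-1.69 ± 0.11). The AP-1 family fell (0.00176, adjusted p = 0.44 with an estimated correlation, 7 of 12, 9 over the list alone, median -1.68), with Atf3 at -3.48 ± 0.52, Fosl1 at -3.44 ± 0.58 and Fos at -2.41 ± 0.45. EGFR ligands and feedback fell (0.00499, adjusted p = 0.44 with an estimated correlation, median -1.17), with 8 falling and 1 rising of 15, 8 and 2 over the list alone. The growth factor genes Hbegf (-2.42 ± 0.35) and Btc (-2.15) were among them.

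Immune signalling lists also fell in keratinocytes. Antigen presentation and interferon-gamma fell (camera adjusted p = 0.000298, adjusted p = 0.44 with an estimated correlation, 11 of 18 by either count, median -1.41). Irf1 fell by 2.51 and B2m, the light chain of MHC class I, by 1.54 ± 0.27. Type I interferon response fell (0.00224, adjusted p = 0.44 with an estimated correlation, median -0.93), with 6 of 14 falling, or 7 with 1 rising adjusted over the list alone, such as Usp18 (-3.27). It was not called within basal (-0.08, 0.491) or suprabasal cells (-0.35, 0.0998). The IL-17 and IL-23 axis fell (0.00224, adjusted p = 0.44 with an estimated correlation, 4 of 10, 6 over the list alone, -0.98), such as the receptor gene Il17rc (-1.18). Inflammatory cytokines and NF-kB feedback fell (0.0346, adjusted p = 0.497 with an estimated correlation, -1.22), with 6 of 15 falling, or 7 with 1 rising over the list alone. Il6 fell by 4.05 ± 0.41 and Ptgs2, the inducible prostaglandin synthase, by 3.24 ± 0.35. Without DKO 2 the cytokine call was lost (adjusted p = 0.111). Outside the hair follicle compartment the interferon (0.0765), IL-17 (0.0992), cytokine (0.108) and terminal differentiation (0.214) calls were lost.

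Dissociation and handling stress genes fell in keratinocytes (camera adjusted p = 5.8e-06, adjusted p = 0.44 with an estimated correlation, 12 of 16, 14 adjusted over the list alone, median -2.05). Fos, Fosb and Atf3 are on this list and on the AP-1 list. The heat shock gene Hspa1a, whose reads its paralog Hspa1b shares, fell by 2.22 ± 0.19, and Btg2 by 2.39. Hypoxia and glycolysis genes fell (0.00224, adjusted p = 0.44 with an estimated correlation, 8 of 18 by either count, -0.53), with the vasodilator gene Adm at -5.35 ± 0.65. Inflammatory fibroblast genes (0.0149, 4 falling and 2 rising of 15, 7 and 2 over the list alone, -1.21) and regulatory and exhausted T cell genes (0.0144, 3 of 6 by either count, -1.10) were called lower, as were tumour-type neutrophil genes (0.0376, 3 of 9, 5 over the list alone, -0.83). Each had an adjusted p = 0.44 with an estimated correlation. Il6 and the vessel growth factor gene Vegfa (-1.73), which keratinocytes also make, were among the members that fell. DNA damage and p53 genes were called lower (0.0404, adjusted p = 0.497 with an estimated correlation, 2 falling and 1 rising of 14, 3 and 1 over the list alone, -0.69).

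Several of these calls were lost when a library was left out. Without Ctrl 1 the inflammatory fibroblast (0.069), regulatory (0.121), tumour-type (0.133) and DNA damage (0.0738) lists lost their calls in keratinocytes. Without Ctrl 2 tumour-type genes lost theirs (0.102), as did tumour-type (0.111) and DNA damage genes (0.06185) without DKO 2. Squamous carcinoma-associated genes were not called (0.854, 3 rising and 3 falling of 16, 3 and 4 over the list alone), with Krt19, a simple-epithelium keratin, at 3.61. Neither were extracellular matrix (0.23, 3 rising and 6 falling of 21, 4 and 8 over the list alone, but 0.0339 without Ctrl 2) or endothelial activation (0.738, 0 rising and 1 falling of 5 by either count). The squamous list (median -0.22, mean 0.35) and endothelial activation (0.10 and -0.18) differ in sign between median and mean.

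Within compartments, whose shares differed between the groups, fewer lists were called. Handling stress genes were called lower in basal, suprabasal and hair follicle cells (medians -1.30, -2.55 and -1.78), as was the AP-1 family (-1.54, -2.35 and -1.62), and NRF2 genes were called higher (0.75, 0.81 and 0.57, the last 0.54 with 2 genes at their bound). Basal and stem cell genes were called lower in basal (-0.64) and hair follicle cells (-0.71), but not in suprabasal cells (-0.60, 0.0536). Antigen presentation was called lower in suprabasal (-0.97, 0.000114) and hair follicle cells (-0.53, 0.0124), but not in basal cells (-0.06, 0.47). EGFR ligands and feedback were called lower in the same 2 compartments (-0.998, 0.00583, and -0.88, 0.000705), while basal cells had a median of 0.05 and a mean of -0.49 (0.47). Inflammatory fibroblast genes were called lower in suprabasal cells alone (-2.20, 0.00652) and extracellular matrix in hair follicle cells alone (-1.27, 0.00196).

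Hypoxia and glycolysis was not called in basal (-0.15, 0.669), suprabasal (0.35, mean -0.13, 0.4) or hair follicle cells (0.02, mean -0.09, 0.794). The IL-17 and IL-23 axis (-0.27, -0.84 and -0.88) was called in none of these compartments, nor were the cytokine (-0.06, -1.53 and -0.64), tumour-type and DNA damage lists. No compartment call held with an estimated correlation (lowest adjusted p = 0.447 with an estimated correlation), and in hair follicle cells no member of any list passed over all genes.

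**Figure D3:**
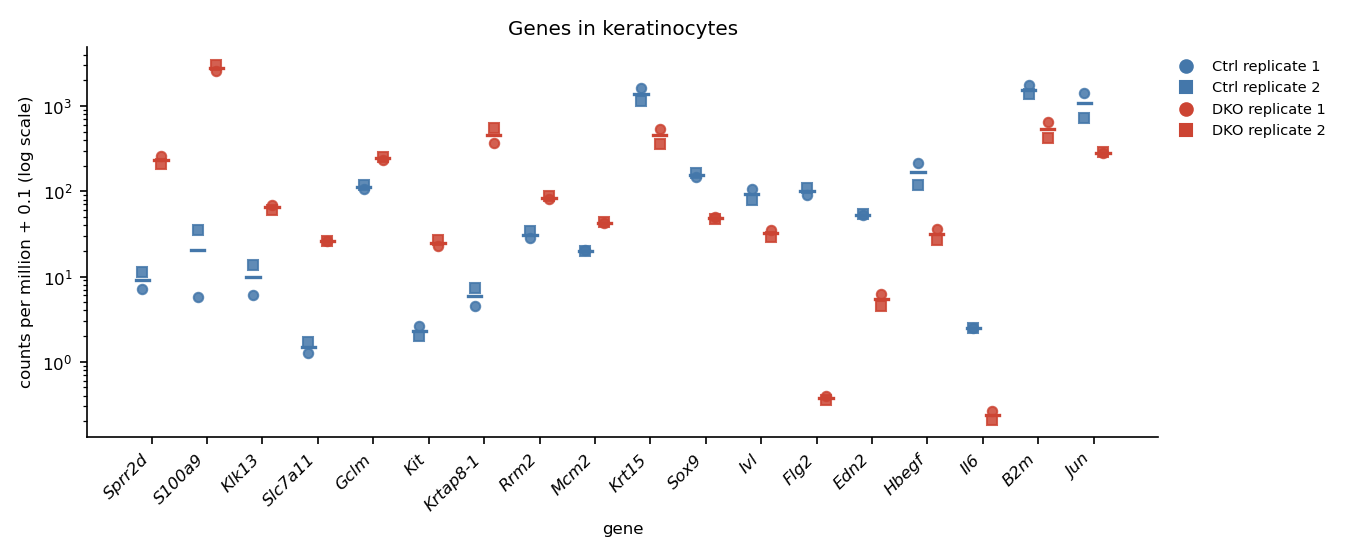
Levels of 18 named genes in keratinocytes of each library, in CPM plus 0.1 on a log scale, with a bar at each group's mean. Flg2 falls from 99.5 to 0.279 and Sprr2d goes from 9.03 to 233.

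Psoriasis-type genes were called higher in each keratinocyte compartment. In suprabasal cells all 22 stood higher (camera adjusted p = 4.25e-11, adjusted p = 0.46 with an estimated correlation, 4 by either count, median 3.50), with Sprr2d up by 5.93 ± 0.56 and the defensin gene Defb4 at least 22.5-fold higher. In basal cells all 16 stood higher (1.66e-09, adjusted p = 0.57 with an estimated correlation, 6 rising, 9 over the list alone, median 2.24), led by S100a9 (9.07 ± 0.30, adjusted p = 0.000808) beside 33294 ± 1310 plain CPM in DKO neutrophils. In hair follicle cells 11 of 12 stood higher (0.0124, adjusted p = 0.566 with an estimated correlation, 0 by either count), with a median of 1.74, or 1.01 with the 7 genes absent or nearly absent from a group at their bound. The suprabasal class did not hold like cells in the groups. Its cluster that leads with Krt77 held 673 and 427 Ctrl against 31 and 8 DKO cells, that with Sprr2b 4 and 56 against 459 and 392, and that with Krt16 9 and 22 against 338 and 125. Basal cells also differed: the cluster that leads with Krt24 and holds Grem1 among its leading genes had 209 and 91 Ctrl against 72 and 23 DKO cells, that with Kcnd3 28 and 29 against 5 and 5, that with Wfdc18 0 and 21 against 126 and 53, and that with Cacna2d3 4 and 1 against 89 and 43. Changes in these 2 classes are thus not shown to lie within like cells. Slc7a11 rose by 6.08 ± 0.50 and 4.93 in these compartments, Edn2 fell by 6.27 ± 0.22 and Flg2 by -7.21 ± 0.56 in suprabasal cells, and Grem1, which blocks BMP signals, fell by 5.39 ± 0.28 in basal cells. In all 1147 genes rose and 1422 fell of 11566 in suprabasal cells, 134 rose and 234 fell of 12025 in basal cells, and 7 rose and 13 fell of 12189 in hair follicle cells. Suprabasal calls numbered 780 without DKO 1 and 476 without DKO 2, where Sprr2d (0.0528 and 0.0698) and Flg2 (0.0514 and 0.0549) were lost, Defb4 was lost without DKO 2 (0.059) and Slc7a11 without Ctrl 1 (0.0536). Without Ctrl 1, Ctrl 2, DKO 1 and DKO 2, basal calls numbered 149, 654, 226 and 130 and hair follicle calls 2742, 1533, 0 and 0. Under a mitochondrial limit of 10%, with no doublets removed, with no filter and by DESeq2 they numbered 1187, 1130, 2143 and 886 in basal and 4605, 4588, 1939 and 230 in hair follicle cells. Under the mitochondrial and doublet settings cells were named again, so these compartments need not hold the same clusters. Basal calls were 811 at resolution 2.0, 602 with thinned counts and 1823 with a crossed pairing.

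In macrophages and monocytes Hp, which encodes haptoglobin, rose to 158 ± 22.7 CPM (4.54 ± 0.38, edgeR adjusted p = 9.77e-05). Chil3, a chitinase-like protein, went from 1 to 711 UMIs (ratio 282, interval 50.4 to 11140), the osteopontin gene Spp1 from 1 to 175 (69.3, 12.3 to 2755) and Lrg1 from 1 to 164 (65.0, 11.5 to 2582). These sizes rest on 1 Ctrl UMI each, and the fitted log2 change of Chil3 ranged from 5.89 without Ctrl 1 to 11.30 without Ctrl 2. DKO neutrophils held 1278 ± 100 plain CPM of Hp, 1154 ± 33.4 of Lrg1, 692 ± 736 of Spp1 and 5.84 of Chil3. Free RNA or doublets with neutrophils are not excluded for Hp, Lrg1 and Spp1. Heat shock genes Dnajb1 (-1.64 ± 0.22) and Hspa1a (-1.78 ± 0.23), the signalling adaptor gene Tank (-1.61 ± 0.21) and the ectonucleotidase gene Entpd1 (-1.49 ± 0.20) fell. A cluster that leads with Chil3, Arg1 and Ly6c2 held 4 and 6 Ctrl against 78 and 54 DKO cells, and another held 45 and 10 Ctrl against 19 and 12 DKO cells, so the class did not hold like cells in the groups. In all 93 genes rose and 193 fell of 8278, with 1590 at an unadjusted p under 0.05. The groups did not overlap in 50.3% of genes (33.3% by chance). With equal numbers of cells per library edgeR called 0 genes (496 at an unadjusted p under 0.05), DESeq2 called 135, thinned counts gave 28, and without Ctrl 2 and DKO 2 the calls numbered 666 and 133.

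Hypoxia and glycolysis genes were called higher as a list in macrophages and monocytes (camera adjusted p = 0.00145, adjusted p = 0.577 with an estimated correlation, 2 of 14, 6 adjusted over the list alone, median 0.67). So were type I interferon response (0.00145, adjusted p = 0.577 with an estimated correlation, 1 of 22, 5 over the list alone, 0.55) and tumour-type neutrophil genes (0.000461, adjusted p = 0.577 with an estimated correlation, 3 of 13 by either count, 0.57), which alone passed fry (0.0145). Neutrophil granule genes were called higher (0.00139, adjusted p = 0.577 with an estimated correlation, 3 of 11, 4 over the list alone, 0.42). Psoriasis-type genes were too (0.00248, adjusted p = 0.654 with an estimated correlation, 2 of 8, 3 over the list alone), with a median of 4.43, or 2.50 with the 4 genes absent from a group at their bound. The protease inhibitor gene Slpi rose by 2.79 ± 0.50 (19.0 to 90.4 CPM) beside 7017 ± 1120 plain CPM in DKO neutrophils. Carry-over from neutrophils is not excluded for Slpi or for the 2 neutrophil lists.

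The AP-1 family fell in macrophages and monocytes (camera adjusted p = 5.96e-05, adjusted p = 0.577 with an estimated correlation, 4 of 12, 8 adjusted over the list alone, median -0.72), with Fosl2 at -1.49 ± 0.21. Handling stress genes fell (5.96e-05, adjusted p = 0.577 with an estimated correlation, 6 falling and 1 rising of 16, 8 and 1 over the list alone, -0.61). This list shares Fos, Fosb and Atf3 with the AP-1 list. Without Ctrl 1 the AP-1 (0.0688), handling (0.109), psoriasis-type (0.109) and interferon (0.233) calls and Slpi (1.54, adjusted p = 0.117) were lost. Neutrophil-attracting factors were not called (0.923, median -0.02, mean 0.24), but were called in opposite directions without Ctrl 1 (0.0289, higher) and without Ctrl 2 (0.0137, lower).

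T cells of DKO skin gained the epithelial cytokine gene Il22, the 1 member of the IL-17 and IL-23 axis that passed. Il22 had 0 UMIs in Ctrl T cells and 145 in DKO (at least 76.8-fold higher, edgeR adjusted p = 0.000183, lost with equal numbers of cells per library at 0.15). A UMI of it was found in 0 of 185 and 0 of 64 Ctrl cells, which allow shares of cells with a UMI, not of cells that express it, of up to 1.62% and 4.69%, and in 5.05% (interval 2.45 to 9.09) and 9.76% (2.72 to 23.1) of DKO T cells. Median depths of those DKO cells were 1135.5 and 5578 UMIs, and DKO keratinocytes held Il22 in 0 of 3693 cells (median depth 2969) and 0 of 2145 (2690). That list was called higher (camera adjusted p = 6.93e-07, adjusted p = 0.447 with an estimated correlation, median 0.86), with 11 of 11 higher, 1 rising, and 5 adjusted over the list alone. Il17a stood at 300 ± 217 and 1478 ± 571 (2.32 ± 0.51, adjusted p = 0.0693), and it passed without each library in turn (1.70, 3.32, 2.68 and 1.87 without Ctrl 1, Ctrl 2, DKO 1 and DKO 2). Of Il22 UMIs 144 lay in the cluster that leads with Il17f and Il17a, which held 6 and 17 Ctrl and 39 and 17 DKO cells. That cluster also held 83.9% of the Il17a UMIs of Ctrl T cells and 94.0% of those of DKO T cells. Within it 9 of 23 Ctrl and 28 of 56 DKO cells held an Il17a UMI, and 0 and 13 an Il22 UMI. A change in the make-up of the class is thus not excluded for the list or for Il17a, and it was not tested.

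Regulatory and exhausted T cell genes were called higher as a list in T cells (camera adjusted p = 0.000986, adjusted p = 0.442 with an estimated correlation, median 0.63), with 2 of 13 rising over all genes and 5 with 1 falling when adjusted over the list alone. The checkpoint receptor gene Pdcd1 rose by 1.86 ± 0.41. The interferon-induced Ifitm1 (2.89 ± 0.35) and Ifitm2 (1.63 ± 0.24), which are close paralogs, and the polyamine oxidase gene Smox (2.14 ± 0.27) rose. Atf3 (-2.98 ± 0.30), Pltp (-3.33 ± 0.35) and Cntn1 (-2.46 ± 0.29) fell, and the macrophage marker Lyz2 went from 658 to 3 UMIs (ratio 138, 47.0 to 671.1). With no doublets removed Lyz2 stood at 0.05, and Pltp (-0.10), Atf3 (adjusted p = 0.103), Pdcd1 (0.258) and Fos (0.0736) lost their calls. RNA of other cells, free or in doublets, is not excluded as the source of Lyz2 and Pltp in Ctrl T cells.

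The AP-1 family fell in T cells (camera adjusted p = 0.00164, adjusted p = 0.447 with an estimated correlation, 3 falling and 1 rising of 10, 5 and 1 adjusted over the list alone, median -0.89), with Fos at -1.42 ± 0.28. Handling stress genes, which also include Fos, fell (9.44e-07, adjusted p = 0.418 with an estimated correlation, 6 of 16, 10 over the list alone, -1.07), with Hspa1a at -1.62. Type 2 immunity genes (0.0471, adjusted p = 0.602 with an estimated correlation, 0 of 5, 2 over the list alone, -1.02) and DNA damage genes (0.0471, adjusted p = 0.658 with an estimated correlation, 0 of 9 by either count, -0.50) were called lower. Neither call held without DKO 1 (0.446 and 0.189) or DKO 2 (0.0725 for each), nor type 2 genes without Ctrl 1 (0.158), DNA damage without Ctrl 2 (0.404), or regulatory genes without DKO 1 (0.0989).

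Cytotoxic lymphocyte genes were not called in T cells (0.481, 0 of 12, 3 falling over the list alone, median 0.05, mean -0.19). Antigen presentation (0.481, 0 rising and 4 falling of 14, 1 and 4 over the list alone, 0.13 and -0.53) and type I interferon response (0.931, 0.24 and -0.04) also differed in sign between median and mean. Antigen presentation was called lower without Ctrl 1 (0.000264) and DKO 2 (0.00144). In all 46 genes rose and 136 fell of 6483, with 1175 at an unadjusted p under 0.05 and no overlap of groups in 49.1% of genes (33.3% by chance). Calls numbered 729, 376 and 318 without Ctrl 2, DKO 1 and DKO 2, 60 under a mitochondrial limit of 10%, 110 by DESeq2, 34 at resolution 2.0, and 19 with thinned counts. The cluster that leads with Trdv4, a receptor segment of epidermal γδ T cells, held 85 and 11 Ctrl against 22 and 2 DKO cells, so the class differed in its cells. Cntn1 is also among the leading genes of that cluster, so its fall is not shown to lie within like cells.

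Type I interferon genes rose together in fibroblasts. All 21 measured members stood higher (camera adjusted p = 4.2e-13, adjusted p = 0.252 with an estimated correlation, fry adjusted p = 0.028), 4 rising over all genes and 17 adjusted over the list alone (median 0.97). They included Ifit3 (14.3 to 47.9 CPM, 1.75 ± 0.16, edgeR adjusted p = 0.0122) and the ubiquitin-like Isg15 (1.17 ± 0.14). The steroid- and toxin-oxidising Cyp1b1 rose by 2.07 ± 0.17, Gngt2 by 2.17 ± 0.20 and Lcn2 by 4.72 ± 0.42. The chemokine gene Cxcl12 rose by 1.82 ± 0.23 and the matrix gene Postn by 1.65 ± 0.23. Cdh4 (-4.50 ± 0.26) and Stac (-3.01 ± 0.22) fell, and the neuropeptide gene Gal was at least 71.4-fold lower (189 and 0 UMIs). Krt77, a keratin of the Ctrl-rich keratinocyte cluster, went from 220 to 1 UMI (ratio 249, 44.3 to 9886), and S100a9 from 1 to 304 UMIs (ratio 268, 47.8 to 10640) beside 33294 ± 1310 plain CPM in DKO neutrophils.

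Psoriasis-type genes were called higher in fibroblasts (camera adjusted p = 0.000861, adjusted p = 0.887 with an estimated correlation, 2 of 8, 5 adjusted over the list alone, median 4.76, or 4.07 with 2 genes at their bound). Proliferation genes (0.000304, adjusted p = 0.887 with an estimated correlation, 0 of 19 by either count, 0.62) and inflammatory fibroblast genes (0.0459, adjusted p = 0.887 with an estimated correlation, 1 of 16, with 4 rising and 1 falling over the list alone, 0.15) were too. Carry-over from keratinocytes or neutrophils is not excluded for the psoriasis-type list or for Lcn2 in fibroblasts. Handling stress genes were called lower (0.000304, adjusted p = 0.887 with an estimated correlation, 4 of 16, 6 over the list alone, -0.59). Extracellular matrix genes were not called (0.111, 1 of 22, with 4 rising and 2 falling over the list alone, 0.15), but were without Ctrl 1 (0.0013). Without Ctrl 1 proliferation (0.727, lower) and psoriasis-type genes (0.444) lost their calls, and inflammatory fibroblast genes did without Ctrl 2 (0.884) and DKO 2 (0.0999).

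In all 45 fibroblast genes rose and 71 fell of 12047, with 2044 at an unadjusted p under 0.05 and no overlap of groups in 50.8% (33.3% by chance). Calls numbered 900, 962, 41 and 26 without Ctrl 1, Ctrl 2, DKO 1 and DKO 2, and DESeq2 called 274. Without DKO 1 and DKO 2 Isg15 (0.121 and 0.122), Postn (0.126 and 0.14) and Cxcl12 (0.0521 and 0.11) lost their calls. With no doublets removed 17 genes passed, and Isg15 (0.0634), Postn (0.0707), Cxcl12 (0.106), Stac (0.0527), Krt77 (0.302) and S100a9 (0.0842) did not.

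Endothelial cells lost heat shock and early-response genes. Hspa1a and Hspa1b, which are paralogs, fell by 3.18 ± 0.24 and 3.14 ± 0.25, Atf3 by 1.95 ± 0.22, the matricellular gene Ccn1 by 1.61 ± 0.18 and Auts2 by 2.13 ± 0.20. The transmembrane collagen gene Col13a1 rose from 15.6 to 185 CPM (3.55 ± 0.29, edgeR adjusted p = 4.29e-06). The prostaglandin transporter gene Slco2a1 rose by 1.75 ± 0.21, the insulin receptor gene Insr by 1.62 ± 0.19 and the matrix protease gene Mmp14 by 1.81 ± 0.22. The tip cell gene Esm1 rose by 3.92 ± 0.54, from 4 to 71 UMIs. The AP-1 family fell (camera adjusted p = 8.44e-10, adjusted p = 0.416 with an estimated correlation, 8 of 10 by either count, median -1.01), as did handling stress genes (1.64e-19, adjusted p = 0.407 with an estimated correlation, 13 of 16, 15 adjusted over the list alone, -1.02). Atf3, Fos and Fosb are on both lists.

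Interferon response was called higher in endothelial cells (camera adjusted p = 0.000251, adjusted p = 0.511 with an estimated correlation, 0 of 20, 5 adjusted over the list alone, median 0.47). Antigen presentation was called higher (0.00146, adjusted p = 0.511 with an estimated correlation, 0 rising and 1 falling of 17, 2 and 1 over the list alone, 0.44). Extracellular matrix was as well (0.0131, adjusted p = 0.572 with an estimated correlation, 4 of 15 by either count, 0.72), a call lost without Ctrl 1 (0.0666), Ctrl 2 (0.195) and DKO 2 (0.405). Endothelial activation genes were not called (0.0941, 3 of 12, 4 over the list alone, 0.22) except without DKO 2 (0.00666). In all 145 genes rose and 172 fell of 8508, with 1426 at an unadjusted p under 0.05 and no overlap in 47.5% (33.3% by chance). Without DKO 1 edgeR called 0 genes, so each gene call named here was lost there, and 30, 195 and 7 passed without Ctrl 1, Ctrl 2 and DKO 2. Slco2a1 (0.0535) and Esm1 (0.0763) were lost without Ctrl 1, and Atf3 (0.0923), Ccn1 (0.0798), Auts2 (0.0648), Mmp14 (0.0655) and Esm1 (0.0518) without DKO 2. DESeq2 called 105, and at resolution 2.0, where 82 passed, Ccn1 did not (0.328).

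**Figure D4:**
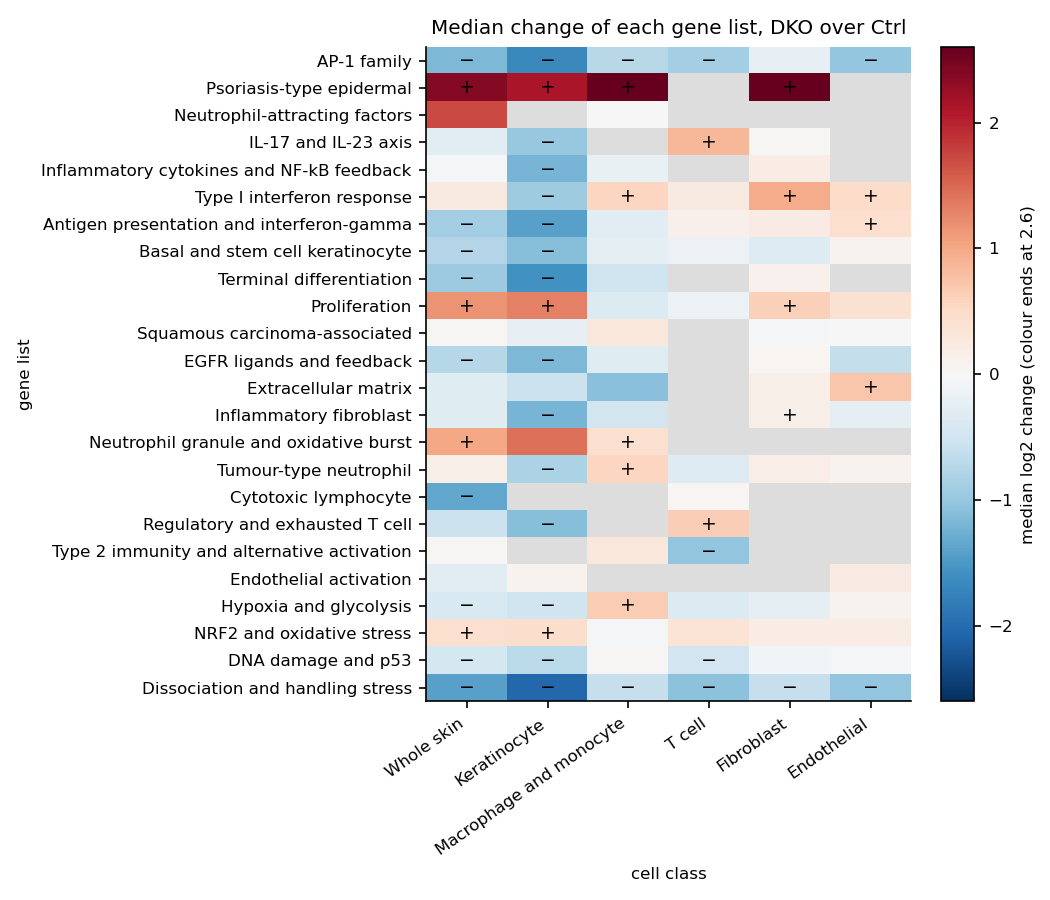
Median log2 change of each gene list in each tested class, with a plus or minus sign where camera called it at the preset correlation and grey where fewer than 5 members were measured. Interferon genes are 0.97 in fibroblasts and -0.93 in keratinocytes.

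Skeletal muscle changed in 24 genes (14 rising and 10 falling of 5835), among them the fatty acid binding gene Fabp5 (4.71 ± 0.26), S100a9 (at least 232-fold higher) and S100a8 (4.56 ± 0.41), which stood beside 33294 ± 1310 and 14987 ± 691 plain CPM in DKO neutrophils, and the AP-1 gene Fosb (-2.81). With no doublets removed Fabp5 (0.295), S100a9 (0.511) and S100a8 (0.289) lost their calls in muscle. Carry-over from other cells is not excluded for these genes. Mural cells lost 6 of 3797 genes, including the stress gene Gadd45b (-4.58 ± 0.58) and the endothelin receptor gene Ednrb (-3.09), but 0 with a replicate block, with equal numbers of cells or with thinned counts, and 67 rose and 44 fell without Ctrl 1. In Schwann cells edgeR called 0 of 4034, with 324 at an unadjusted p under 0.05 and 4 by DESeq2. Without Ctrl 1, DKO 1 and DKO 2 muscle calls numbered 10, 68 and 119, mural calls without Ctrl 1, Ctrl 2, DKO 1 and DKO 2 numbered 111, 67, 117 and 55, and Schwann calls 53, 48, 6 and 14.

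Neutrophils were too few in Ctrl to be tested, and their levels show which signals they carried in DKO skin. In 290 DKO neutrophils the neutrophil-attracting chemokine Cxcl2 stood at 51299 ± 12514 plain CPM and the cytokine Il1b at 22172 ± 2085, with a UMI of Il1b in 288 cells. They held 84.0% of Cxcl2 UMIs and 87.6% of Il1b UMIs of DKO skin, where Ctrl skin had 53.3% of Cxcl2 in macrophages and monocytes and 48.8% of Il1b in dendritic and Langerhans cells. Cxcl3 stood at 3994 ± 322, Ccl3 at 3769 ± 909 and Osm at 1027 ± 99.8, with 90.7%, 65.9% and 64.2% of UMIs in neutrophils, and Il23a at 154 ± 46 with 63.6%. Granule genes of immature neutrophils were scarce, with 0 UMIs of Mpo, Elane and Camp, 3 of Ngp and 6 of Ltf.

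Other inflammatory genes came from other cells. Fibroblasts held 85.1% of Cxcl1 and 72.8% of Cxcl5 UMIs in DKO skin, T cells 99.9% of Il17a in Ctrl and 98.9% in DKO, and keratinocytes 97.7% of Il1f6, 89.8% of S100a8 and 87.0% of S100a9. Of S100a9 neutrophils held 11.6%, at 33294 ± 1310 plain CPM. Arg1 lay in keratinocytes in Ctrl skin (92.9%) and in macrophages and monocytes in DKO skin (83.6%, 506 UMIs). None of these shares was tested between groups.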

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

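Of the tests below, those of a deletion in keratinocytes alone, of milder handling and of the hair cycle were chosen only after the result was seen.

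Jun fell further in keratinocytes than in several other classes when both were fitted together. The difference from fibroblasts was -2.062 (adjusted p = 0.0159), from macrophages and monocytes -1.865 (3.39e-09) and from skeletal muscle -1.881 (6e-05), while those from endothelial cells (-0.77, 0.217) and T cells (-0.67, 0.224) did not pass. Junb fell further in keratinocytes than in macrophages and monocytes, by -1.013 (0.00293), and T cells, by -1.16 (0.00269), while the differences from fibroblasts (-0.93, 0.105), endothelial cells (0.00, 1) and muscle (-0.21, 1) did not pass. A cluster without a name that leads with Sct, Tgm6 and Krt90 held 225 cells in DKO and 0 in Ctrl skin. It scored highest as keratinocytes and missed that name by the naming rule, so it is not shown to be a class of its own. The same holds for a larger cluster without a name that leads with Cxcl9, Aldh3a1 and Fst. That cluster held 219 and 178 Ctrl and 208 and 37 DKO cells.

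The 3 patterns weighed are the lower Jun and Junb, the keratinocyte genes, and S100a8 and S100a9 outside their usual cells. For the first, an equal fall in every class is argued against by the difference of -2.062 ± 0.207 between keratinocytes and fibroblasts. A deletion in keratinocytes alone is argued against as the whole cause by Junb in endothelial cells, which fell by -1.304 ± 0.178, a call lost without DKO 1 (0.12) or DKO 2 (0.108) and with thinned counts, where the change shrank to -0.73 ± 0.33 and its error grew (0.289). Milder handling of the DKO libraries may add to the fall, since both genes answer to digestion. Heat shock genes outside the AP-1 family had a median under -0.3 in 7 of the 7 tested classes outside keratinocytes, from -0.62 in muscle to -1.98 in endothelial cells. Jun did not follow the heat shock genes in every class. It fell in endothelial cells and T cells (heat shock median -1.18). It did not pass in macrophages and monocytes (-1.64), fibroblasts (-0.96) or muscle, and stood slightly higher in fibroblasts and muscle. A drop of Jun and Junb through the deletion, the biological explanation that the design names, stays open beside milder handling as untested.

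For keratinocytes, hair follicle cells that were mostly in DKO could account for many calls. But 37.94% of the 3324 called genes, 1261, were called in the same direction in suprabasal cells alone, against a bound of 20%, and 25 in the opposite one. Independent lists would share 320 genes in the same direction, but suprabasal cells are a part of the same sums, so some agreement was given beforehand. In basal cells it was 8.755% (291 genes), but only 368 genes were called there in all, so the bound could not be reached. Of the called keratinocyte genes tested in basal cells 2679 of 2950 kept their sign, and 1 was called in the opposite direction. In keratinocytes outside the hair follicle compartment the part called in the same direction was 20.126% (669). The suprabasal agreement argues against cells named as hair follicle as the whole cause for those 1261 genes only, and the rest stay open. Suprabasal clusters also differed between groups, and some of them carried the hair follicle markers Cst6 and Krt79. A hair cycle difference that does not come from the genotype could not be told apart from the genotype: the Ctrl libraries differed by 5.406 times in hair follicle share, and the group means by 6.168 times. With 2 libraries per group, and different shares and clusters under a mitochondrial limit of 10%, neither reading is excluded. Both ratios also rest on the naming of clusters with Cst6 and Krt79 as suprabasal. They leave out the unnamed clusters that scored highest as keratinocytes.

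S100a9 rose in fibroblasts (1 to 304 UMIs, adjusted p = 0.0122, lost with no doublets removed at 0.0842), endothelial cells (1 to 57, 0.000753, lost without Ctrl 1 at 0.0763, DKO 1 at 0.303 and DKO 2 at 0.0655) and muscle (0 to 287), and S100a8 in endothelial cells (0 to 50, 0.00319, lost without each library in turn) and muscle, but not in fibroblasts (6 to 197, 0.126). In T cells S100a9 went from 1 to 39 UMIs and S100a8 from 0 to 37, untested. Free RNA from keratinocytes and neutrophils could be the source, and 1 source would hold both genes at 1 ratio in every class. The S100a9 part of their UMIs ranged over 11.74 percentage points between these classes in DKO 1 and 9.684 in DKO 2. In DKO 1 it went from 52.1% in endothelial cells (interval 40.0 to 63.9) to 63.8% in muscle (56.2 to 70.9). These intervals overlap and both hold the 59.5% of whole skin, so counting error alone can give that range. Macrophages and monocytes, not among the classes set beforehand, had 60.7% in DKO 1. In DKO 2 they had 37.0% (interval 26.6 to 48.5), which 1 ratio would not give. DKO 1 lies between the bounds of 10 and 20 points set beforehand and DKO 2, over 3 classes since T cells had too few UMIs, under 10. With so few UMIs per class these bounds could not test for 1 ratio, so free RNA and expression in these cells cannot be told apart.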

How the results depend on the processing

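The tests of keratinocytes outside the hair follicle compartment, of whole skin without hair follicle cells or without neutrophils, of a crossed pairing and of thinned counts for gene counts were chosen only after the result was seen. All other alternatives were planned.

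Of 210 shares outside the main results 201 kept their direction and side of the threshold, of 1974 values of named genes 1672, and of 1118 list tests 943, with 250 genes and 138 lists no longer past it and 49 genes and 33 lists newly past it. The cause was not tested for any change below except where the construction gives it. The change of the neutrophil share ranged from 3.41 at resolution 0.5 to 4.56 with the top 8% of doublet scores removed, and from 3.60 to 4.92 when a library was left out. Classes with a changed share numbered 1 in each alternative except without Ctrl 1 and Ctrl 2 (0, range 0 to 1). Changed compartments numbered 1, but 2 under the mitochondrial limit of 10%, with at least 500 genes and with no doublets removed, 0 at resolution 0.5, 0 with a replicate block, and 0 to 2 when a library was left out.

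Counts of genes moved more. In whole skin 0 became 10 with a replicate block, 362 with no filter, 2733 by DESeq2, 724 with thinned counts, 1 without hair follicle cells, 0 without neutrophils, and 0 to 5150 when a library was left out. In keratinocytes 3324 became 910 outside the hair follicle compartment, and 0 to 5544 when a library was left out. In macrophages and monocytes 286 became 596 with no filter, 135 by DESeq2, 0 with equal cells per library, 28 with thinned counts, and 133 to 666 when a library was left out. In T cells 182 became 362 with the block, 607 with no filter, 110 by DESeq2, 60 under the mitochondrial limit of 10%, 34 at resolution 2.0, 54 with equal cells, 19 with thinned counts, and 251 to 729 when a library was left out. In fibroblasts 116 became 43 with the block, 1097 with no filter, 274 by DESeq2, 17 with no doublets removed, 199 with thinned counts, and 26 to 962 when a library was left out. In endothelial cells 317 became 149 with the block, 679 with no filter, 105 by DESeq2, 82 at resolution 2.0, 203 with equal cells, 66 with thinned counts, and 0 to 195 when a library was left out.

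The replicate numbers are not shown to pair the libraries. A crossed pairing gave 472, 1, 482, 508, 517 and 761 genes in whole skin, keratinocytes, macrophages and monocytes, T cells, fibroblasts and endothelial cells, where the block by number gave 10, 4440, 356, 362, 43 and 149.

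Called lists numbered 53 of 112, but 0 with an estimated correlation and 3 with fry, and 48 to 59 when a library was left out. The estimated correlation also missed every changed list in the simulations, so its count of 0 says little about these lists. Jun in keratinocytes ranged from -2.34 to -1.32 when a library was left out and was -1.83 with the block (adjusted p = 0.0274). Junb ranged from -1.92 to -0.63 and passed by DESeq2 (-1.43), under the mitochondrial limit of 10% (-1.49) and with thinned counts (-1.25), but not with the block (-1.28, adjusted p = 0.0565).

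Directions that reversed were few. When a library was left out, adjusted p ranged from 2.33e-06 to 0.727 for proliferation in fibroblasts, from 0.0137 to 0.977 for neutrophil-attracting factors in macrophages and monocytes, and from 0.00414 to 0.531 for extracellular matrix in whole skin, each turning without Ctrl 1 (0.727, 0.0289 and 0.0382). With no doublets removed, basal and stem cell genes turned in T cells (adjusted p = 0.0124, range 0.0124 to 0.985 over alternatives), Mgst1 in hair follicle cells passed at -0.57 (from 2.01, adjusted p = 0.0311) and Lyz2 in T cells 0.0477. Krt83 in hair follicle cells was -0.53 with equal cells per library (from 2.06). Depth limits rest on class size: neutrophils of Ctrl skin numbered 10, so that no test of their genes was run.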

Other observations

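The test of milder handling named here was chosen only after the result was seen. Gene changes in hair follicle, suprabasal and basal cells come from the same edgeR test as in the results above.

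Beyond the chemokines, DKO neutrophils carried signals not described so far, in plain CPM with SD over the 2 libraries. The checkpoint ligand gene Cd274 stood at 626 ± 254 and held 44.0% of the gene's UMIs in DKO skin, Ptgs2 at 2315 ± 544 with 41.6%, Csf3r, the receptor of their growth factor, at 1691 ± 12.3 with 79.0%, and Cd14, a receptor for bacterial lipopolysaccharide, at 7175 ± 1151 with 63.0%. Siglecf, a marker of some tumour-resident neutrophils, had 16 UMIs. Neutrophils fell into 3 clusters with 0, 2, 47 and 75 cells, 4, 4, 37 and 56 cells, and 0, 0, 71 and 4 cells in Ctrl 1, Ctrl 2, DKO 1 and DKO 2, so that 1 of them came mainly from DKO 1.

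Hair follicle cells of DKO skin showed 20 changed genes, among them the hair shaft genes Gprc5d (3.65 ± 0.28), Krtap8-1 (3.47), the hair keratin gene Krt83 (2.06) and the detoxifying gene Mgst1 (2.01), which rose, while Dnah8 (-3.53), Bach2 (-2.74), Krt79 (-3.84), a keratin of sebaceous ducts, and Alox12e (-2.40) fell. Every call in this compartment was lost without DKO 1 and without DKO 2, and Mgst1 (0.06) and Bach2 (-0.79) also lost theirs under a mitochondrial limit of 10%. With no doublets removed Mgst1 passed in the other direction (-0.57, adjusted p = 0.0311), and Krt83 stood at -0.53 with equal numbers of cells (adjusted p = 0.635). Under that mitochondrial limit and with no doublets removed cells were named again, so the compartment need not hold the same clusters. In suprabasal cells the kinase gene Prkcq (3.73 ± 0.18), Prss12 (2.72 ± 0.16) and Akr1c18 (3.33 ± 0.20) rose, Fyb2 had a ratio of 152 (41.5 to 1257), and Cyp3a13 (-4.00) and Rarres1 (-2.36) fell. In basal cells, whose clusters also differed between the groups, Mgst1 (2.93 ± 0.16) and Porcn (3.16 ± 0.20) rose, and Serpinb11 (-4.56) and Lmo7 (-3.37) fell.

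Heat shock genes that are not AP-1 members had a median below 0 in each tested class outside keratinocytes, a pattern that milder handling of the DKO libraries could give (7 of 7 classes with a median under -0.3). The medians were -1.64 in macrophages and monocytes, -1.18 in T cells, -0.96 in fibroblasts, -1.98 in endothelial cells, -0.62 in muscle, -1.76 in mural cells and -1.08 in Schwann cells, and -0.78 in keratinocytes. The mitochondrial share of UMIs also moved with the groups, at 5.64% and 4.09% in Ctrl and 2.75% and 2.41% in DKO. The genotype and the handling of single libraries were not separated by the design.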
